A study of Mus musculus with 6 samples.

How the data were processed

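RNA abundance was measured by stranded total RNA sequencing after ribosomal RNA depletion in 6 mouse libraries. Per the labels' protocols, cells carrying a floxed Mdm2 allele on a p53-null background were transduced with a retrovirus for CreERT2, a Cre recombinase that 4-hydroxytamoxifen (4-OHT) activates, together with GFP, or for GFP alone, and then given 4-OHT or ethanol vehicle. The labels do not say which vector the cells of each library carried. The labels give 3 cell types, which are T cell lymphoma, sarcoma and fibroblasts from ear tissue, with 1 library labelled Mdm2 deleted and 1 labelled vehicle for each. Exposure lasted 6 h for the lymphoma and 48 h for the sarcoma and the fibroblasts, per the labels. No library is labelled as GFP-only cells given 4-OHT, so the labelled deletion and the 4-OHT exposure coincide in every comparison. Groups were taken from the labels alone. Because the values go against the labels of cell type and against a loss of Mdm2 RNA, groups are called "the library labelled X" throughout.

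Each deposited file held, per transcript, the estimated counts and the TPM that the authors obtained with kallisto 0.43.0 and GRCm38, per the submitters' processing notes. The strand setting and the transcript set were not given in the sources used here. The 76055 targets of the files were joined by transcript identifier to GENCODE M21 (GRCm38), and 75049 matched a gene. The other 1006 targets held 0.393% to 0.410% of the estimated counts of a library and were left out. Of the 51165 matched protein-coding targets, 94.1% had exactly the coding length of the annotated transcript, so reads in untranslated regions were not counted for these targets. Noncoding targets had the full annotated length in 95.6% of cases. Estimated counts were summed over the targets of each gene and rounded to whole numbers, and the deposited TPM values were summed per gene for alternatives. Kallisto shares reads between near-identical sequences by likelihood, so values of paralogs such as Tgtp1 and Tgtp2, Ifit3 and Ifit3b, or Eif3j1 and Eif3j2 are uncertain as a split.

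Total estimated counts per library lay between 26243064 and 37517726. A count of 0 was taken to allow up to 3 counts (per library or over the pair, as stated), which is 0.0797 to 0.113 TMM-scaled CPM per library. Intervals and floors cover counting error only, since PCR copies were not told apart.

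Because each group holds 1 library, no p-value was computed within a labelled pair. For each pair the log2 ratio of TMM-scaled CPM + 0.5 was taken, genes with a mean of at least 5 CPM over both libraries were counted when they differed at least 2-fold, and the ratio of TMM-scaled CPM of named genes, with no pseudocount, was given a 95% Clopper-Pearson interval from the counts. Gene lists were described by the median log2 ratio of members with at least 1 CPM and its percentile among 10000 random lists matched on mean expression in 20 bins. Log2 ratios were correlated across genes between labelled pairs, which share no library. Genes are not independent replicates, so no p-value accompanies these correlations.

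The shared effect was tested over all 6 libraries with edgeR 4.0.16 (quasi-likelihood test, two-sided, TMM, filterByExpr by arm, Benjamini-Hochberg adjusted p under 0.05), with the cell type label as a block. This left 2 residual degrees of freedom, to which the test added 9.23 prior degrees of freedom estimated over all genes. The labelled cell types served as the replicates. Each SE of a shared log2 fold change is its absolute value divided by the square root of the edgeR F statistic. Nothing in the labels says that the 6 libraries came from separate cultures beyond the cell type names, so p-values measure the spread between these libraries, technical or biological. The pairing comes from the labels. Deviations from the arm means correlated at -0.0603, 0.221 and 0.199 within the labelled pairs. Gene lists, fixed with the named-gene rule before the data were examined, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry. With an estimated correlation, camera tests on the 2 residual degrees of freedom and has little power here. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.

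On simulated counts for the shared comparison (15780 genes, 200 changed), the fit recovered 74% of genes changed by 0.5 on the log2 scale, 90% at 1, 98% at 2 and 100% at 3, and 4.74% of its calls were false. In simulated pairs, every gene changed at least 4-fold and no unchanged gene was counted at the 2-fold limit. The simulation gave every gene the same dispersion, 0.00267, with no cell type effect and changes balanced in sign. In the data 49.6% of genes were called, so these rates check the procedure and are not error rates for the data.

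Named genes followed a fixed rule. Mdm2, Mdm4, Trp53, Trp63 and Trp73 were given in every comparison. Each pair contributed the 8 protein-coding genes with the largest increase and the 8 with the largest decrease at a mean of at least 5 CPM, leaving out predicted genes without a functional symbol, and not every gene so selected is printed. Each described list contributed up to 4 members with the largest absolute change at a mean of at least 1 CPM. The shared effect contributed the 10 genes per direction with the lowest p among those past the threshold. Alternatives comprised other scalings (library totals, DESeq2 size factors, protein-coding genes only), TPM, other pseudocounts and expression minimums, DESeq2 and limma tests, no filter, no block, and leaving out each labelled pair. They were chosen before the data were examined.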

Results

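The series asked how gene expression differs after Mdm2, which encodes the ubiquitin ligase that restrains p53, is deleted in cells without p53. Total RNA was profiled in 6 mouse libraries, 1 per combination of 3 labelled cell types (fibroblast, T cell lymphoma, sarcoma) and 2 labelled arms (Mdm2 deleted, vehicle). The pair labelled fibroblast had 30084324 estimated counts in the library labelled deleted and 28967548 in the library labelled vehicle. The pair labelled lymphoma had 26243064 and 29549223, and the pair labelled sarcoma 27981244 and 37517726. There is no replicate within a group, so differences within a pair carry no test. Coordinates are on GRCm38.

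The targeted gene was examined before any other comparison. Mdm2 (ENSMUSG00000020184.15, chromosome 10, 117688875 to 117710758) was not lower in the libraries labelled deleted. It stood at 30.5, 31.1 and 31.1 CPM in the libraries labelled fibroblast, lymphoma and sarcoma deleted, against 28.4, 28.0 and 28.5 CPM in the matching libraries labelled vehicle. The shared log2 fold change was 0.13 ± 0.05 (SE, 3 labelled pairs), with an edgeR adjusted p of 0.0539, and it passed the threshold as higher without the cell type block and with protein-coding genes only. The deposited values give no read positions, so they do not show whether part of the coding sequence was removed. Trp53, which encodes p53 (ENSMUSG00000059552.13, chromosome 11, 69580359 to 69591873), was counted at 22.3 to 28.5 CPM in all 6 libraries although the labels call the cells p53-null, and its shared log2 fold change was 0.08 ± 0.07 (edgeR adjusted p = 0.414). For Trp53 too, the values do not show which part of the gene was read, so these counts do not test the p53-null label. Mdm4, the Mdm2 homologue, had a shared log2 fold change of 0.04 ± 0.05 (edgeR adjusted p = 0.571). Trp63, a p53 family member, fell from 1.21 ± 0.375 CPM to 0.255 ± 0.169 CPM (SD, n = 3 libraries per arm, edgeR adjusted p = 0.000177), on 2 to 11 counts per library labelled deleted and 28 to 62 per library labelled vehicle. Trp73 had 0 counts in every library. All directions below therefore run from libraries labelled vehicle to libraries labelled deleted, labels that the Mdm2 values do not bear out.

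Cell type markers placed all 6 libraries in the same mesenchymal profile. Col1a2 and Col3a1, which encode fibrillar collagen chains, stood at 3458 and 2163 CPM in the library labelled lymphoma deleted and at 5088 and 5292 CPM in the library labelled lymphoma vehicle, close to 3390 and 2163 CPM and 4948 and 5311 CPM in the fibroblast-labelled libraries. The 7 genes of the T cell receptor complex (Cd3d, Cd3e, Cd3g, Cd247, Trac, Trbc1 and Trbc2) summed to 0 counts over the pair labelled lymphoma, which allows up to 3 counts over the pair. They summed to 1 count in the pair labelled fibroblast and 6 in the pair labelled sarcoma. Ptprc, the pan-leukocyte marker, reached at most 0.506 CPM, in the library labelled sarcoma deleted. Of 15 skeletal muscle genes, 0 reached 1 CPM in any library. Over 9873 protein-coding genes, libraries of the same labelled arm had a log2 CPM difference with an SD of 0.1 to 0.145 whatever their cell type label, against 0.531 to 0.544 for libraries of different arms. The labelled arm accounted for 92.9% of the sum of squares, the cell type label for 4.02% and the remainder for 3.05%.

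**Figure D1:**
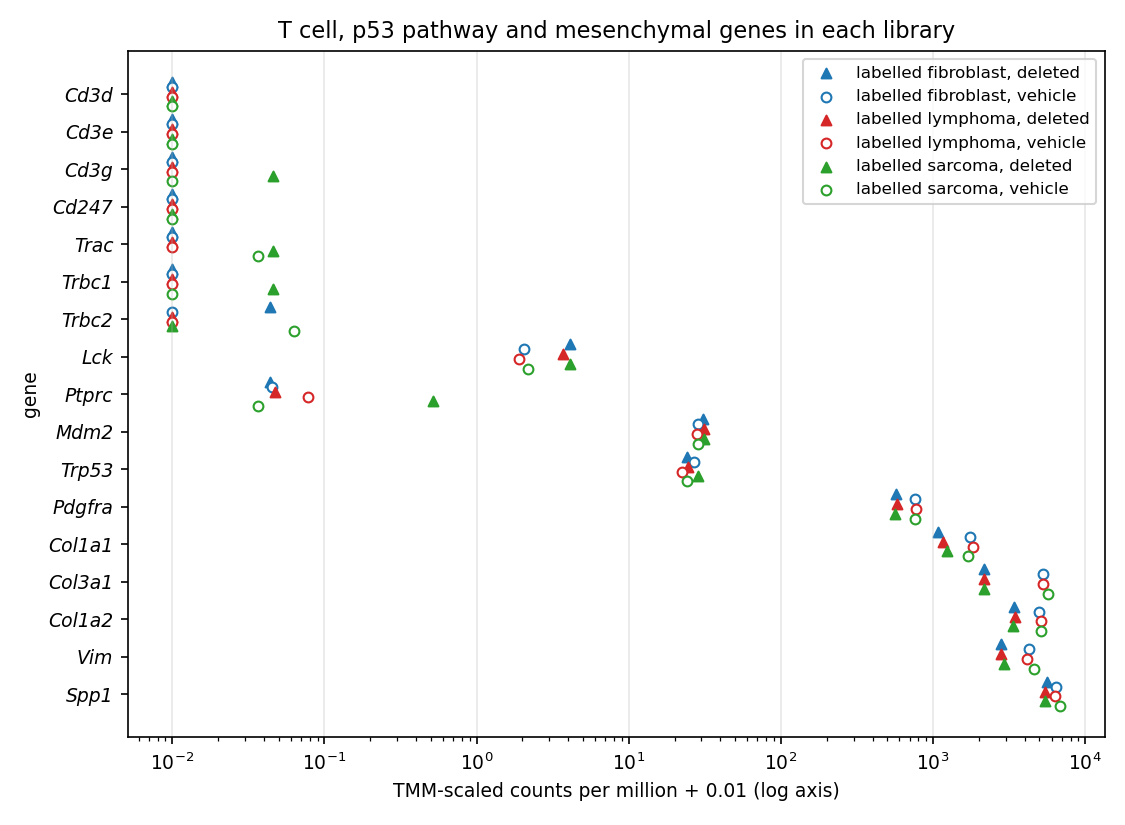
TMM-scaled CPM + 0.01 (log axis) of T cell, p53 pathway and mesenchymal genes in each of the 6 libraries, 1 point per library; filled triangles are libraries labelled deleted and open circles libraries labelled vehicle. Points of the 3 labelled cell types lie close together within each arm for Col1a2 and Mdm2, while low-count genes such as Ptprc spread, and the T cell receptor genes sit at or near 0 in the libraries labelled lymphoma as in the others.

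In the pair labelled fibroblast, the genes most raised in the library labelled deleted were interferon-induced. Cxcl10, a chemokine for activated T cells (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889), stood at 367 CPM against 6.32 CPM. Acod1, which makes itaconate, stood at 36.4 against 0.351 CPM, and Slfn2, Gbp5, Ifit3b, Rsad2, Oas3 and Tgtp1 had log2 ratios of 4.64 to 5.11. The largest decreases were in Agtr2, an angiotensin receptor, at 1.05 against 16.3 CPM, and in Dkk2, a secreted Wnt regulator, at 21.8 against 109 CPM. Cthrc1, Osr2, Ogn, Crhr1, Tmem86a and Rab3il1 followed, with log2 ratios of -2.07 to -1.67. Of 10841 genes with a mean of at least 5 CPM, 300 were at least 2-fold higher and 64 at least 2-fold lower in the library labelled deleted. Mdm2 had a CPM ratio of 1.08 (95% counting interval 0.977 to 1.18), Mdm4 a log2 ratio of 0.11, Trp53 of -0.14 and Trp63 a CPM ratio of 0.0690 (0.00797 to 0.274, on 2 and 28 counts). The interferon response list had a median log2 ratio of 3.31 and the list of ATF4 targets for amino acid supply 0.55, both at percentile 100 of random lists. Extracellular matrix genes had a median of -0.37 (percentile 0), with Col11a1 at 98.0 against 269 CPM and Col12a1 at 158 against 395 CPM. Genes of the mitochondrial genome had a median of -0.47 (percentile 0), led by mt-Atp8 at 92.6 against 177 CPM. Over all libraries labelled vehicle, mt-Atp8 averaged 124 ± 45.3 CPM (SD). The library labelled fibroblast vehicle also held the largest share of ribosomal RNA, 3.61% against 0.570 to 2.40% in the others, and a link was not tested.

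The pair labelled lymphoma, with 6 h of exposure per the labels, gave much the same ranking. Cxcl10 stood at 366 CPM in the library labelled deleted against 6.08 CPM, Acod1 at 39.1 against 0.506 CPM and Mx1, an antiviral GTPase, at 50.9 against 0.911 CPM. Tgtp2, Slfn2, Rsad2, Gbp5 and Ifit3b had log2 ratios of 4.73 to 4.96. Agtr2 stood at 0.752 against 17.2 CPM and Dkk2 at 21.3 against 111 CPM, and Cthrc1, Ogn, Crhr1, Osr2 and Angptl7 had log2 ratios of -2.19 to -1.68. Among 10874 genes, 303 were at least 2-fold higher and 75 at least 2-fold lower. Mdm2 had a CPM ratio of 1.11 (95% counting interval 1.01 to 1.22), with log2 ratios of -0.05 for Mdm4 and 0.12 for Trp53, and Trp63 had a CPM ratio of 0.297 (0.118 to 0.663, on 8 and 30 counts). The interferon list had a median of 3.27 and the NF-kB target and cytokine list 1.39 (percentile 100 for each), the latter led by Ccl5 at 77.3 against 2.87 CPM. Replication-dependent histone genes had a median of -0.62 (percentile 0), with Hist1h4k at 129 against 247 CPM. The mitochondrial genome list stood at 0.03 (percentile 63.4).

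In the pair labelled sarcoma, Cxcl10 stood at 445 CPM in the library labelled deleted against 7.67 CPM and Gbp5 at 88.6 against 1.94 CPM, while Ccl5, a chemokine of the NF-kB list, had a log2 ratio of 4.78. Acod1, Slfn2, Ifit3b, Tgtp1 and Oas2 completed the 8 largest increases, at log2 ratios of 4.69 to 5.67. Dkk2 stood at 21.8 against 114 CPM and Agtr2 at 1.12 against 17.3 CPM, and Cthrc1, Crhr1, Ogn and Angptl7 had log2 ratios of -2.15 to -1.86. Eif3j2 had 0 counts (up to 0.108 CPM) against 14.2 CPM, but it has the near-identical copy Eif3j1, so the value is uncertain. Of 10856 genes, 306 were at least 2-fold higher and 75 at least 2-fold lower. Mdm2 had a CPM ratio of 1.09 (95% counting interval 0.997 to 1.20), with log2 ratios of 0.05 for Mdm4 and 0.24 for Trp53, and Trp63 had a CPM ratio of 0.241 (0.115 to 0.462, on 11 and 62 counts). Medians were 3.29 for the interferon list, 1.46 for the NF-kB list and 0.47 for the ATF4 list (percentile 100 for each), against -0.40 for extracellular matrix and -0.47 for histones (percentile 0 for each).

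The labelled pairs resembled one another gene by gene. Log2 ratios correlated across genes at Pearson r = 0.947 between the pairs labelled fibroblast and lymphoma, 0.921 between fibroblast and sarcoma and 0.938 between lymphoma and sarcoma. Of 10713 genes with at least 5 CPM in all 3 pairs, 256 were at least 2-fold higher and 45 at least 2-fold lower in every pair, and 0 were 2-fold higher in a pair and 2-fold lower in another. The sign was shared by all 3 pairs for 74.5% of these genes, where 25% is the share for independent signs. Libraries of an arm differed little whatever their cell type label. This likeness therefore cannot tell a response common to 3 cell types from repeated libraries of 1 cell population.

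**Figure D2:**
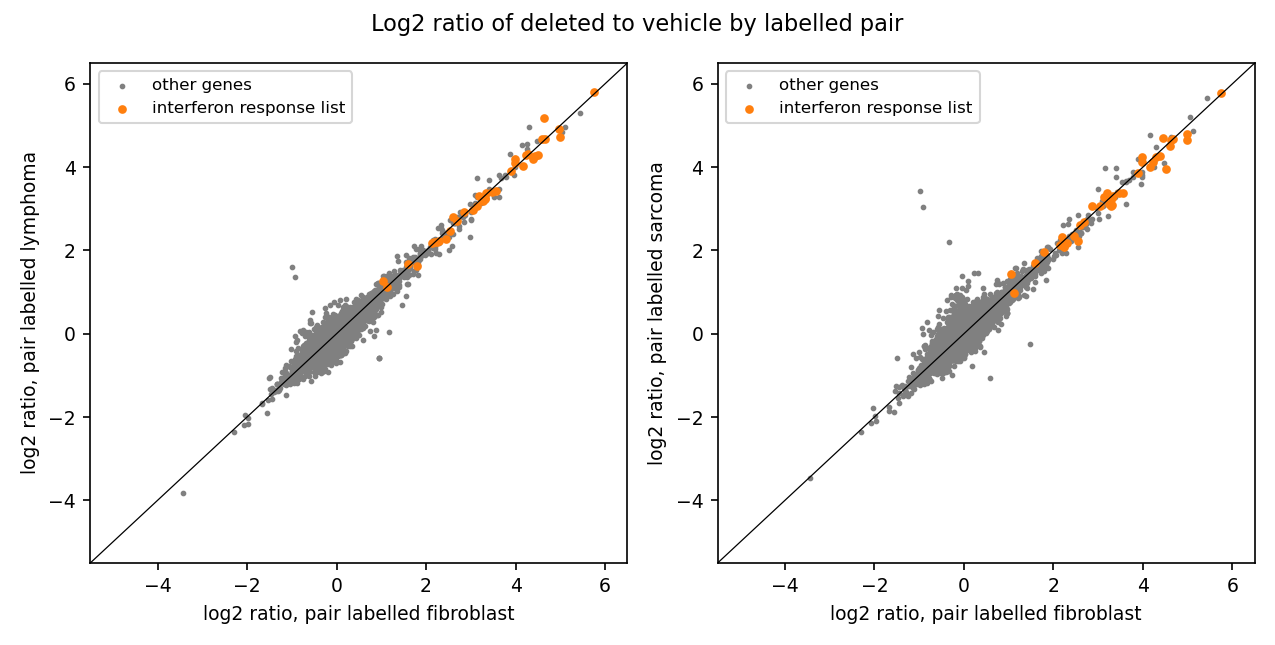
Log2 ratio of TMM-scaled CPM + 0.5, library labelled deleted over library labelled vehicle, for genes with at least 5 CPM in all 3 pairs; the pair labelled fibroblast is on the x axis, the pairs labelled lymphoma (left) and sarcoma (right) are on the y axes, and the line marks equal ratios. Interferon response genes (orange) lie along the line at the upper end, with Cxcl10 near 5.8 in each pair.

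Tested over the 3 labelled pairs, interferon-induced genes led the shared effect. Cxcl10 rose from 6.69 ± 0.861 to 393 ± 45.7 CPM (SD, n = 3 libraries per arm), a log2 fold change of 5.88 ± 0.06 (SE), with an edgeR adjusted p of 5.24e-14. Oas3, which activates RNase L (chromosome 5, 120753098 to 120777661), rose from 4.31 to 122 CPM, and Ifit3 (chromosome 19, 34583531 to 34588731) from 43.4 to 1059 CPM. The guanylate-binding proteins Gbp3 and Gbp2 rose from 25.3 to 500.2 and from 31.9 to 598 CPM, and Ifit1, Ifit3b, Ifi44, Tgtp1 and Oasl1 by 3.91 to 4.93. Dkk2 (chromosome 3, 132085292 to 132180304) fell from 111 ± 2.48 to 21.6 ± 0.273 CPM, with an edgeR adjusted p of 2.39e-12. Col3a1 (chromosome 1, 45311538 to 45349706) fell from 5417 to 2159 CPM, Col12a1 from 386 to 161 CPM and Col11a1 from 254 to 99.9 CPM. Agtr2 had a log2 fold change of -4.11 and Cthrc1 of -2.21, while Rab3il1, Adamts1, Lrrc17 and Plau fell to values between -1.73 and -1.19. Of 15933 genes tested, 3981 rose and 3920 fell at an edgeR adjusted p under 0.05, of which 760 and 224 changed at least 2-fold. With DESeq2 the counts were 2541 and 2488, and with limma on log2(TPM + 1) they were 2352 and 1552, a share of higher calls of 60.2% in place of 50.4%.

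Several immune and stress response lists had most of their tested members risen. All 39 interferon response genes rose (39 adjusted over the list alone), with a median log2 fold change of 3.35, led by Cxcl10, Mx1 (5.25), Rsad2 (4.94) and Ifit3b (4.90). camera gave an adjusted p of 2.67e-28, and adjusted p = 0.233 with an estimated correlation. All 25 tested NF-kB targets and cytokines rose (25 adjusted over the list alone), with a median of 1.63, among them Ccl5 (4.70), Icam1 (3.70), Cxcl2 (3.67) and Mmp13 (3.57). camera gave 4.78e-14 for this list, and adjusted p = 0.233 with an estimated correlation. Of 34 ATF4 targets, 31 rose and 1 fell (33 and 1 adjusted over the list alone), with the cystine transporter Slc7a11 at 1.90, Atf3 at 1.71, Chac1 at 1.58 and Slc7a3 at 1.26 (camera adjusted p = 7.05e-11, and adjusted p = 0.508 with an estimated correlation). Of 25 immediate early genes, 15 rose and 5 fell (15 and 6 adjusted over the list alone), among them Egr2 (2.23), Klf4 (1.67) and Egr1 (1.53). The endoplasmic reticulum chaperone list had 13 of 21 members risen and 1 fallen (13 and 1 adjusted over the list alone), with Hspa5 at 0.50, and the NRF2 target list 14 of 25 risen and 4 fallen (14 and 4 adjusted over the list alone), with Hmox1 at 1.19. camera gave adjusted p values of 0.0271, 0.00626 and 0.0225 for immediate early, chaperone and NRF2 genes, each at adjusted p = 0.508 with an estimated correlation. The NRF2 call was lost without the pair labelled fibroblast (adjusted p = 0.0616).

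Targets shared by the p53 family moved in both directions. Of 23 apoptosis genes of this kind, 13 rose and 3 fell (13 and 3 adjusted over the list alone), among them the death receptor Fas (1.73), the BH3 protein Bid (1.47), Shisa5 (1.26) and Eda2r (1.15), with camera adjusted p = 0.0161 and adjusted p = 0.508 with an estimated correlation. Within the pairs labelled fibroblast, lymphoma and sarcoma, the apoptosis list had medians of 0.19, 0.19 and 0.11. These stood at percentiles 99.2, 98.4 and 88.3 of random lists, so the pair labelled sarcoma was not in the upper tail. Of 30 arrest and repair targets, 12 rose and 13 fell (14 and 13 adjusted over the list alone). For these, camera gave adjusted p = 0.686, while fry called the list higher (adjusted p = 0.0115). Tap1, which loads peptides for MHC class I and is also interferon-induced, rose by 2.26 on the log2 scale, Gdf15 by 1.66 and Cdkn1a, the p21 gene, by 1.63, from 1.48 ± 0.567 to 4.47 ± 0.219 CPM. Of 8 CDK inhibitors, Cdkn1a rose and 7 fell (1 and 7 adjusted over the list alone), including Cdkn1c (-0.89), Cdkn2b (-0.76, lost without the pair labelled sarcoma) and Cdkn2a (-0.48), with camera adjusted p = 0.0119 and adjusted p = 0.508 with an estimated correlation. Of 4 tested members of the p53 family core list, Trp63 fell and the others did not pass (camera adjusted p = 0.976). Among 4 antiapoptotic BCL2 genes, Bcl2l1 (0.27) and Mcl1 (0.12) rose, the latter lost under DESeq2 size factors and without the pair labelled fibroblast or sarcoma (camera adjusted p = 0.968), and the median turned from 0.03 to -0.04 on TPM. DNA damage checkpoint genes split into 9 risen, with Atm at 1.48, and 8 fallen of 28 (10 and 9 adjusted over the list alone). Here camera gave adjusted p = 0.686, while fry called the list higher (adjusted p = 0.0133).

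Matrix, lipid, histone and ribosomal lists were lower in the libraries labelled deleted. Of 30 extracellular matrix genes, 17 fell and 4 rose, led by Col11a1 (-1.35), Col3a1 (-1.33), Col12a1 (-1.26) and Postn (-0.93), with camera adjusted p = 0.00259 and adjusted p = 0.508 with an estimated correlation. Of 62 replication-dependent histone genes, 59 fell, with a median of -0.45 and Hist1h1b going from 336 to 210 CPM (camera adjusted p = 5.04e-11, adjusted p = 0.508 with an estimated correlation and 0.0607 with fry). Histone medians were -0.24, -0.62 and -0.47 in the pairs labelled fibroblast, lymphoma and sarcoma, where small noncoding RNA held 10.9, 8.46 and 9.96% of counts in the libraries labelled deleted against 10.6, 11.6 and 10.8% in those labelled vehicle. Of 80 cytosolic ribosomal protein genes, 64 fell and 1 rose (68 and 1 adjusted over the list alone), with a median of -0.16 and Rpl3 at -0.44 (camera adjusted p = 3.06e-09, and adjusted p = 0.508 with an estimated correlation). Sterol synthesis genes fell in 18 of 26 cases and rose in 3, among them Tm7sf2 (-0.56) and Lss (-0.52), and fatty acid synthesis genes fell in 8 of 13 and rose in 1, among them Scd2 (-0.64) and Acss2 (-0.57). camera gave adjusted p values of 0.000683 and 0.0156 for these, each at adjusted p = 0.508 with an estimated correlation. Mitosis genes fell in 22 of 45 cases and rose in 3, with Spc25 at -0.43 and Pttg1, the securin gene, at 0.96, and hypoxia and glycolysis genes fell in 18 of 28 and rose in 5 (19 and 5 adjusted over the list alone), with Adm at -0.86. camera gave 0.00443 and 0.00626 for these, each at adjusted p = 0.508 with an estimated correlation. Nuclear oxidative phosphorylation genes fell in 20 of 43 cases and rose in 2 (camera adjusted p = 0.00336, and adjusted p = 0.634 with an estimated correlation and 0.0912 with fry), with Ndufb10 at -0.37 and Cycs at 0.69. Where no second count is given in this report, the count adjusted over the list alone was equal. Shared medians of these lists kept their sign under DESeq2 size factors, TPM and protein-coding scaling, while summed TPM turned the nuclear oxidative phosphorylation median in the pair labelled lymphoma from -0.10 to 0.041.

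Lists without a camera call included DNA replication, with 15 risen and 10 fallen of 43 (16 and 11 adjusted over the list alone, camera adjusted p = 0.388), where Gins3 (0.73) and Mcm10 (0.64) rose. Contractile genes fell in 7 of 14 cases and rose in 2, with Lmod1 at -1.19 (camera adjusted p = 0.101). Of 13 mitochondrially encoded genes, mt-Nd3 (-0.29) and mt-Nd6 (-0.22, lost without the pair labelled fibroblast) fell (1 fallen adjusted over the list alone, camera adjusted p = 0.388). Among markers of cell types, 10 of 17 mesenchymal genes fell and 2 rose, with Dcn at -0.83 and Pi16 at 1.01 (camera adjusted p = 0.00589, and adjusted p = 0.508 with an estimated correlation). Of 6 T cell list members tested, Gata3, Lck and Lef1 rose by 1.12, 0.96 and 0.58 on the log2 scale, at no more than 4.25 CPM on average in the libraries labelled deleted, while Thy1 and Notch1, the latter named after its value was seen, fell (camera adjusted p = 0.676). The 3 endothelial genes tested rose (camera adjusted p = 0.0118, and adjusted p = 0.508 with an estimated correlation). Flt1 went from 26.9 to 63.1 CPM, while Pecam1 and Vwf, named after their values were seen, were under 1 CPM in every library. The median of this endothelial list was 1.23, and 0.18 with limma on log2(TPM + 1). Of 5 macrophage list genes, Cd68 rose from 4.72 to 6.56 CPM and Cd14 fell from 22.2 to 19.0 CPM, while Csf1r (1.30) and Itgam, both under 1 CPM in every library and named after their values were seen, also rose (camera adjusted p = 0.0580, and 0.0471 without the pair labelled sarcoma). Ebf1 alone was tested of the B cell list and fell by 0.39 on the log2 scale (camera adjusted p = 0.202). Epithelial genes had Krt8 (2.58) and Krt18 (1.32) risen and Trp63 fallen among 6 (camera adjusted p = 0.510), and chondrocyte and melanocyte genes had 3 of 4 risen, with Col2a1 at 2.47 (camera adjusted p = 0.124). The 1 skeletal muscle gene tested, Acta1, did not pass (camera adjusted p = 0.968).

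**Figure D3:**
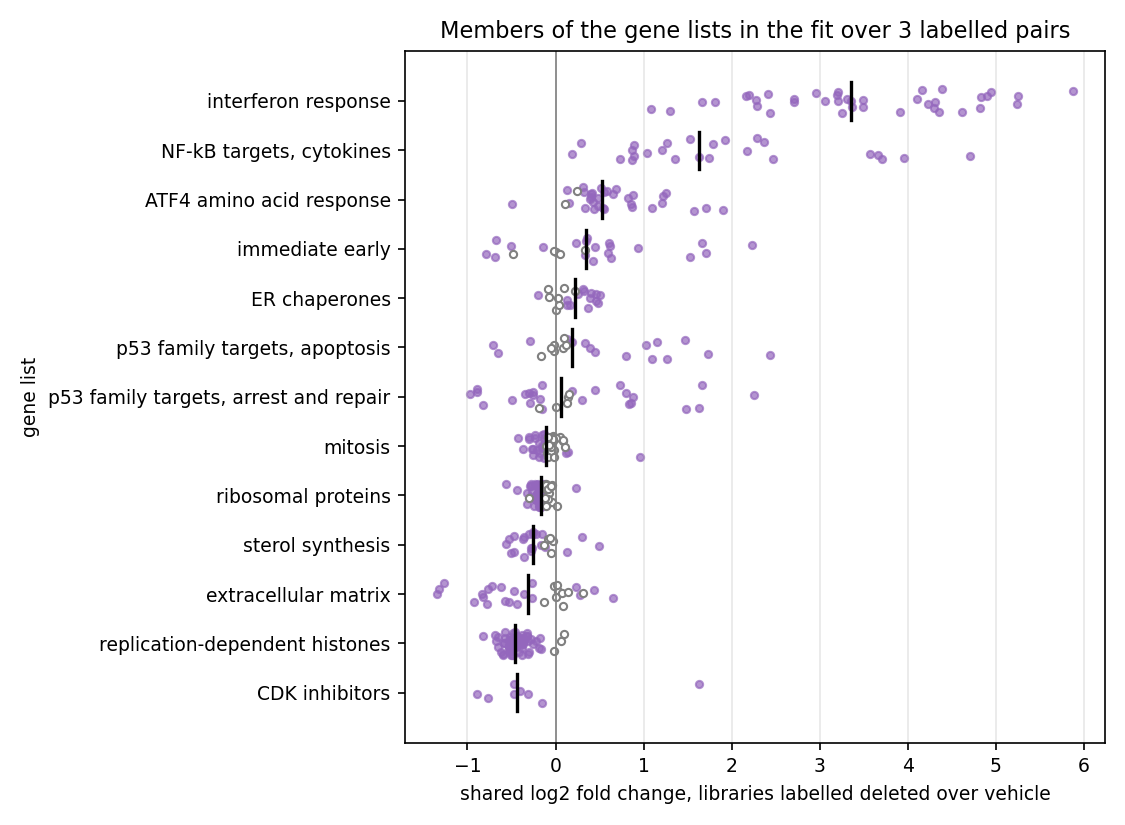
Shared log2 fold change of libraries labelled deleted over libraries labelled vehicle (x axis) for members of 13 gene lists (y axis); each point is a gene, filled where the edgeR adjusted p was under 0.05 and open otherwise, and black bars mark list medians. The interferon list has its median at 3.35 and the histone list at -0.45.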

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

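Chosen only after the result was seen were the tests of T cell receptor counts, of Mdm2 loss and its removed part, and of immune RNA, scaling and 4-OHT.

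Among targets with no gene match, which the comparisons above do not use, 116 had at least 5 CPM, of which 1 was at least 2-fold higher in all 3 libraries labelled deleted and 1 at least 2-fold lower. Opposite signs between single labelled pairs were seen for 5 results, and the differences were not tested. Mdm4 had log2 ratios of 0.1124, -0.0504 and 0.05 in the pairs labelled fibroblast, lymphoma and sarcoma, and Trp53 had -0.14, 0.12 and 0.24. In the same order, medians were -0.0020, 0.0447 and -0.0074 for antiapoptotic BCL2 genes, 0.0835, 0.0896 and -0.0096 for DNA replication, and -0.4683, 0.0282 and 0.1014 for mitochondrially encoded genes.

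The libraries labelled fibroblast, T cell lymphoma and sarcoma shared a mesenchymal profile. T lymphoma cells diluted by stromal cells would bring T cell receptor RNA, and the 7 receptor genes summed to 0 counts over the pair labelled lymphoma. A library sequenced or deposited more than once would give a mean chi-square per gene near 1 or lower, and the lowest within an arm was 2.57. Separate libraries from 1 culture could give higher values, so this test does not cover them. Cell type labels that do not describe the libraries may account for the profile. Values go against the label T cell lymphoma. The pair labelled lymphoma had those 0 receptor counts, and Col3a1 stood there at 2163 CPM (deleted) and 5292 CPM (vehicle). Libraries labelled fibroblast and sarcoma had a log2 CPM difference with an SD of 0.123 (deleted) and 0.1298 (vehicle). Libraries labelled lymphoma differed from the others of their arm by 0.1 to 0.145. These values argue against distinct cell types under the labels fibroblast and sarcoma. Which of these labels describes the libraries, if either does, stays open. Deviations from the arm means correlated at 0.12 on average within labelled pairs, above the highest value across pairs, 0.0781 (lowest -0.249). That lead does not decide whether the libraries of a labelled pair share an origin. The pair labelled fibroblast had -0.0603, against 0.221 and 0.199 in the pairs labelled lymphoma and sarcoma. Shared handling of a pair would also give such values.

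Mdm2 RNA was not lower in the libraries labelled deleted. Loss of the whole Mdm2 RNA in most cells would give a log2 fold change below -1, and it was 0.13 ± 0.05 (SE). Removal of part of the coding sequence could leave the rest counted, and 2566 estimated counts lay on the full-length coding target over the 3 libraries labelled deleted. This explanation stays open because the deposited values hold no read positions. No biological explanation was tested.

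Interferon response genes were higher in the libraries labelled deleted. RNA of immune cells would bring Ptprc, which reached at most 0.506 CPM there: it had 14 counts against 1 in the pair labelled sarcoma but 1 against 1 in the pair labelled fibroblast, where the interferon median was 3.31 against 3.29. Among macrophage genes, Cd68 and Csf1r rose by 0.48 and 1.30 on the log2 scale and Itgam had 29, 16 and 15 counts in the libraries labelled fibroblast, lymphoma and sarcoma deleted against 0, 0 and 1 in those labelled vehicle, but in the same order Lyz2 had 0, 0 and 4 against 0, 0 and 1 and Tyrobp 0, 1 and 2 against 0, 0 and 0. Library scaling left the list's median at 3.17 or more under the scalings run. Activation by 4-OHT or CreERT2 apart from Mdm2 loss could raise these genes too. Of the libraries analysed, 0 are labelled as vector-only cells given 4-OHT, and the labels do not give the vector of each library. This activation and Mdm2 loss therefore cannot be told apart.

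Of the 10 splits of the 6 libraries into 3 and 3, only 1, the labelled arms, gave as many genes as the 7901 called, and the highest other gave 0. Only 4 of the 10 splits, the labelled arms among them, part all labelled pairs. Every other split leaves the difference between the arms in the residual, so few calls there were likely in advance. With 10 splits the smallest share is 0.1, too large for a share under 0.05.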

How the results depend on the processing

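All alternatives here were planned before the data were examined. Changing the mean required from 5 to 1 CPM moved the genes at least 2-fold higher and lower to 459 and 106 (fibroblast), 458 and 122 (lymphoma) and 470 and 128 (sarcoma). At 20 CPM they were 189 and 31, 192 and 32, and 191 and 31, since fewer genes enter. A pseudocount of 5 CPM, which shrinks ratios, left 30, 31 and 34 lower genes, and summed TPM gave 113 lower genes in the pair labelled fibroblast. Genes changed in common numbered 2541 higher and 2488 lower with the DESeq2 Wald test and 2352 and 1552 with limma on log2(TPM + 1), where 4 of the shared calls were opposite, and the cause was not tested. Leaving out each labelled pair gave 3256 to 3540 higher and 3185 to 3949 lower genes. Gene list calls fell to 0 higher and 0 lower for camera with an estimated correlation. Estimates ran from -0.418 (endothelial) to 0.817 (histones). They were 0.571 for ribosomal proteins, 0.410 for nuclear oxidative phosphorylation and 0.320 for ATF4 targets. For histones and these 3 lists, camera p-values at the preset 0.01 therefore rest on a correlation well below the estimate. The loss of calls does not measure correlation alone: the NF-kB list lost its call at an estimate of 0.00776, below the preset 0.01. In contrast, fry called 14 higher lists and lost the nuclear oxidative phosphorylation (adjusted p = 0.0912) and histone lists (adjusted p = 0.0607). It also called 8 lists that camera at 0.01 did not. These were arrest and repair targets, DNA damage checkpoint and contractile genes, and the T cell, macrophage, B cell, epithelial, and chondrocyte and melanocyte lists. Summed TPM moved the median of all genes in the pair labelled lymphoma by 0.14 and turned that of nuclear oxidative phosphorylation genes to 0.041, which is below that shift. Correlations of log2 ratios between cell types (fibroblast and lymphoma, fibroblast and sarcoma, lymphoma and sarcoma) were 0.962, 0.940 and 0.957 at 20 CPM, 0.773, 0.730 and 0.710 with summed TPM, and 0.858, 0.823 and 0.855 as Spearman coefficients, the cause not tested. Without the pair labelled fibroblast the NRF2 list call ended (adjusted p = 0.0616). Mdm2 passed the threshold without the block and with protein-coding genes only, at log2 fold changes of 0.13 and 0.14. Of the other alternatives for the main comparisons, 71 kept their direction and side of the threshold or stayed within 1.5 times the count. Each group holds 1 library, so genes near the floor of 3 counts are limited by depth.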

Other observations

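The 4 gene lists of this part were chosen only after the shared result was seen, so their counts are not independent of it.

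MHC class I antigen presentation genes rose in 17 of 17 cases in edgeR, with a median log2 fold change of 1.51. H2-T23, a nonclassical class I gene, went from 35.0 to 208 CPM, the immunoproteasome genes Psmb9 from 6.57 to 33.1 CPM and Psmb10 by a log2 fold change of 2.16. Genes that sense foreign RNA or DNA rose in 10 of 15 cases and fell in 1, with a median of 1.1 and Zbp1 going from 4.78 to 99.1 CPM, Tlr3 from 1.22 to 13.9 CPM and Ifih1 from 21.3 to 177 CPM. Ifnb1, the interferon beta gene, stood at 1.66, 1.43 and 2.06 CPM in the libraries labelled fibroblast, lymphoma and sarcoma deleted, on 49, 38 and 57 counts, and at 1 or 2 counts in each library labelled vehicle.

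Complement genes rose in 7 of 9 cases and fell in 1, with a median log2 fold change of 0.21, among them Cfb from 4.16 to 91.7 CPM, C4b from 2.02 to 15.9 CPM and C3 from 258 to 638 CPM. Wnt pathway genes fell in 10 of 17 cases and rose in 2, with a median of -0.66, and besides Dkk2 and Cthrc1 these included Rspo2 (-1.11), which enhances Wnt signalling, and the receptor gene Fzd8 (-1.08). The medians of these 4 lists kept their sign under DESeq2 size factors, TPM and protein-coding scaling, but with limma on log2(TPM + 1) they were -0.19 for the Wnt, 0.36 for the complement, 0.74 for the sensing and 1.47 for the MHC class I list.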
